A study of Drosophila melanogaster with 5 samples.

How the data were processed

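The series holds 5 microarrays of RNA from Drosophila melanogaster neurons that were sorted by flow cytometry for green fluorescent protein (GFP). The fluorescence came from a Gal4 driver with regulatory DNA of the choline acetyltransferase gene, the enzyme that makes acetylcholine, so that the sorted cells are described by the labels as cholinergic neurons. Per the labels, 4 arrays (replicates a, b, c and d) hold neurons from cultured embryonic cells and 1 array (replicate a) holds neurons from dissociated larval brain, with total RNA as the starting material in each. The labels do not say whether the 4 embryo culture arrays came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No pair of arrays shared more than 14 identical values, so no array was taken for a copy of another.

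The deposited table gives 1 linear signal intensity per probe set and array, on a 1-colour short oligonucleotide array with control probe sets. The values themselves show that the authors scaled each deposited array to a common mean: after trimming 2% of the probe sets at each end, the mean intensity lay between 500.06 and 500.08 on all 5 arrays. The software, the background correction and the hybridisation protocol are not given in the sources used here, and the table holds no detection calls. The median signal was 222, 235, 206 and 256 on embryo culture arrays a to d and 207 on the larval brain array. The table has 14010 probe sets, of which 44 are controls and 13966 were tested. The array's annotation gives 12443 of them 1 gene symbol, 327 several symbols and 1196 none, and no gene was named from a probe set with several. Symbols were updated through Entrez identifiers to a RefSeq gene table on Drosophila Release 6 for 12394 probe sets, which changed 0 symbols. Genes that the annotation does not name are unnamed here, which says nothing of their presence on the array. No coordinates are given, since the build behind the array's annotation is not stated in the sources used here.

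Intensities were put on a log2 scale after adding 47.4, the 20th percentile of all values, and kept on the authors' scale, with no filter on dim probe sets. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend, two-sided), and p-values were adjusted by Benjamini-Hochberg over all 13966 probe sets with a threshold of 0.05. Because the larval brain group has 1 array, the spread came from the embryo culture arrays alone, with 3 residual degrees of freedom (9.11 after moderation), and the lone larval brain array is assumed to vary like them. A gene with several probe sets was represented by the one with the highest mean of the 2 group means. This left 10844 genes, of which 1209 had several probe sets. Tables were prepared with Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. Differences are larval brain minus embryo culture throughout, with their standard error (SE).

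Before the data were examined, 30 gene lists were fixed: markers of cholinergic and other neurons, synaptic and channel genes, progenitor and cell cycle genes, and markers of glia, muscle, blood cells, fat body, gut, epidermis and germline, with stress, immune and hormone response genes. Each list was tested with limma's camera, which compares its members with all other genes, using a preset correlation between genes of 0.01 and Benjamini-Hochberg over the 30 lists. Camera with an estimated correlation and fry were run beside it. The genes named were the 12 largest rises and 12 largest falls among genes with an adjusted p under 0.05, a higher group mean above 224.8 (the median of all values) and a larval brain value outside the embryo culture range. Up to 4 members per list were named as well: those past the threshold with the largest change, otherwise those with the highest level, and every measured member of the acetylcholine list. Genes known only by a CG number may be given as a count.

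With no detection calls, background was set after the data were seen, as the highest signal among 23 control probe sets for bacterial, yeast and mouse sequences on each array. It was 148, 200, 119 and 271 on embryo culture arrays a to d and 82.6 on the larval brain array. A gene at or under it on every array of a group has only a bound there, and the ratio of the brighter group's mean to it is then given as "at least N-fold". Above it lay 59.6%, 53.8%, 61.9% and 48.6% of the probe sets on the embryo culture arrays and 68.0% on the larval brain array. The number of arrays limits the precision: the median SE of a log2 difference was 0.58, and no difference under 1.35 passed the test.

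The fit was tested on simulated data made from the embryo culture means and spreads, in 20 runs of 13966 probe sets with 200 of them changed in each run. The changed probe sets were drawn from those above the median embryo culture level, so the rates below do not cover dim probe sets. Every simulated array, the lone one included, varied independently by probe set with no array-wide effect. The share of unchanged probe sets among the calls therefore does not cover such an effect. Simulated values under the log2 of the pseudocount of 47.4 were set to it, which cuts large falls short. It recovered 0% of the 2-fold changes, 6.2% of the 4-fold, 34.0% of the 8-fold, 49.6% of the 16-fold and 65.8% of the 64-fold changes, and 3.8% of its calls were unchanged probe sets. A simulated list of 20 independent probe sets shifted by 1 log2 unit was called in 20 of 20 runs with the preset correlation and in 0 of 20 with an estimated one. A missed call with an estimated correlation is therefore weak evidence against a list in a design of this size. The runs did not test the preset correlation of 0.01 on genes that vary together, where it can call too many lists. Among the lists it called in the real data, the estimated correlation ran from -0.0215 (pan-neuronal) to 0.635 (hemocyte).

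The alternatives tried were pseudocounts at the 5th and 40th percentile, quantile normalization, median centring, a filter on dim probe sets, limma without the trend or with robust variances, leaving out each embryo culture array, the mean over a gene's probe sets, other list tests, and a count by fold and range with no test. Added after the data were seen were fits with embryo culture arrays c and d alone, with a and b alone, and with an index of the control transcripts' 3′ to 5′ ratios, of the same with 5′ signals under background set to background, or of their 3′ to middle ratios as a covariate.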

Results

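Transcript levels were measured on 5 arrays of GFP-sorted cholinergic neurons of Drosophila melanogaster, 4 from embryonic cell cultures (embryo culture, replicates a to d) and 1 from dissociated larval brain. Values are probe set intensities on the authors' scale, given for embryo culture as the mean ± SD of 4 arrays. The larval brain values come from 1 array and have no replicate.

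Both sources carried the cholinergic transcripts ChAT and ChT above background on every array. So did Ddc, Vmat, ple and VGAT, the brightest of 10 measured genes for other transmitters. No array holds cells from outside the GFP sort, so these levels do not test the sort. ChAT, the enzyme that makes acetylcholine and the source of the driver used for sorting, had an intensity of 2450 ± 680 (SD, n = 4) in embryo culture and 2255 in larval brain. The log2 difference was -0.07 ± 0.45 (SE), with a limma adjusted p of 0.961. ChT, a choline transporter gene, stood at 873 ± 407 in embryo culture and 1072 in larval brain, a log2 difference of 0.39 ± 0.57 (adjusted p = 0.791). Ace, which encodes acetylcholinesterase, stood at 180 ± 109 and 351, a log2 difference of 0.98 ± 0.83 (adjusted p = 0.628), with 1 embryo culture array, d, under background at 40.2. The vesicular transporter gene VAChT is not named by the array's annotation. Of the 3 measured members of this list 0 passed the threshold, over all probe sets or adjusted over the list alone, and their median difference was 0.74 against embryo culture arrays a and b and -0.10 against c and d. None of the 10 measured acetylcholine receptor genes passed either. The highest of them were nAChRalpha2 with 1088 ± 275 in embryo culture and 1219 in larval brain, and nAChRbeta2 with 1285 ± 203 and 1012. With SEs of this size, differences of several fold in these genes were not detectable.

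Larval brain neurons carried far more transcript of ImpE2, Syp and 3 Bearded family genes than embryo culture neurons, and far less of Muc26B, GstE1, IM33 and Tsp42Ed. The ecdysone-inducible gene ImpE2 rose from 99.3 ± 84.0 in embryo culture, at or under background on all 4 arrays, to 15984 in larval brain, at least 90.9-fold higher (log2 difference 6.91 ± 0.70, limma adjusted p = 0.000963). Muc26B, annotated as a mucin, fell from 13650 ± 6181 to 14.2, which is background, at least 152-fold lower (log2 difference -7.68 ± 0.57, adjusted p = 0.000303). GstE1, a glutathione S-transferase, fell from 39300 ± 8558 to 206 (log2 difference -7.25 ± 0.50, adjusted p = 0.000216).

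Among the 12 largest rises, Syp, which encodes an RNA-binding protein, was at least 34.1-fold higher in larval brain, with 60.9 ± 41.0 in embryo culture and 5996 in larval brain (adjusted p = 0.00262). The Bearded family genes E(spl)m4-BFM, Tom and E(spl)malpha-BFM, which act in Notch signalling, rose as well. E(spl)m4-BFM, at or under background on all embryo culture arrays, was at least 19.2-fold higher (adjusted p = 0.0046), and Tom and E(spl)malpha-BFM had log2 differences of 4.66 ± 0.61 and 4.21 ± 0.71. The homeodomain transcription factor gene pros rose from 257 ± 138 to 3835 (log2 difference 3.86 ± 0.77, adjusted p = 0.0293). The serpin gene Spn43Aa, the translation elongation factor gene eEF1alpha2, nw, Jhbp2, MTA1-like and CG15522 completed this group. Spn43Aa, Jhbp2 and CG15522, at or under background in embryo culture, were at least 13.5-fold, 8.07-fold and 6.84-fold higher, and the log2 differences of nw, eEF1alpha2 and MTA1-like were 5.16, 4.20 and 4.01. The call of MTA1-like (adjusted p = 0.0436) was lost without array a, b or d, that of pros without c or d and that of eEF1alpha2 without d, with adjusted p-values up to 0.0963, 0.079 and 0.079 over the 4 fits that leave out an array. Of 16 alternatives, 10 ended the call of MTA1-like, 7 that of pros and 5 that of eEF1alpha2. With an index of 3′ bias as a covariate, described with the RNA quality values, 7 of these 12 rises stayed past the threshold for a 3′ to middle index, 2 (ImpE2 and Syp) for a 3′ to 5′ index and 0 for the latter floored at background. Their median log2 difference went from 4.44 to 4.05, 3.98 and 3.72 in these fits and their median SE from 0.70 to 0.87, 1.09 and 1.98, so most calls ended with lower precision. With the 3′ to middle index the difference itself shrank most for eEF1alpha2 and MTA1-like, to 2.73 ± 0.85 and 2.43 ± 0.92. With the floored index that of ImpE2 shrank most, from 6.91 to 3.93 ± 1.72, and those of eEF1alpha2 and MTA1-like went to 2.14 ± 2.32 and 1.53 ± 2.46. Adjusted p-values of the 12 ran from 0.00498 to 0.249, 0.0191 to 0.509 and 0.341 to 0.83.

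Among the 12 largest falls, the immune-induced gene IM33 fell from 13840 ± 5946 to 28.1, at least 157-fold (adjusted p = 0.000217). Tsp42Ed, a tetraspanin gene, fell from 14780 ± 1639 to 38.4, at least 178-fold (log2 difference -7.43 ± 0.38, adjusted p = 0.000136). The gene hoka, which encodes a smooth septate junction protein, fell from 5000 ± 2276 to 12.3, at least 56.1-fold (adjusted p = 0.000421), and Srg2 fell at least 76.9-fold (adjusted p = 0.000558). A further 6 genes of this group have only CG numbers. The largest fall among them was that of CG43896, from 20940 ± 6488 to 21.2, at least 243-fold (log2 difference -8.20 ± 0.50). With an index of 3′ bias as a covariate, all 12 falls stayed past the threshold for the 3′ to middle and the 3′ to 5′ index, and 2 of them (IM33 and CG5506) for the floored index. Their median log2 difference went from -7.24 to -7.03, -7.00 and -6.82 in these fits and their median SE from 0.50 to 0.42, 0.56 and 1.24. Some shrank with the floored index: Srg2 from -6.61 to -3.09, hoka from -6.30 to -3.79 and Muc26B from -7.68 to -4.69. Adjusted p-values of the 12 ran from 3.73e-05 to 0.000284, 8.98e-05 to 0.00183 and 0.0446 to 0.367.

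**Figure D1:**
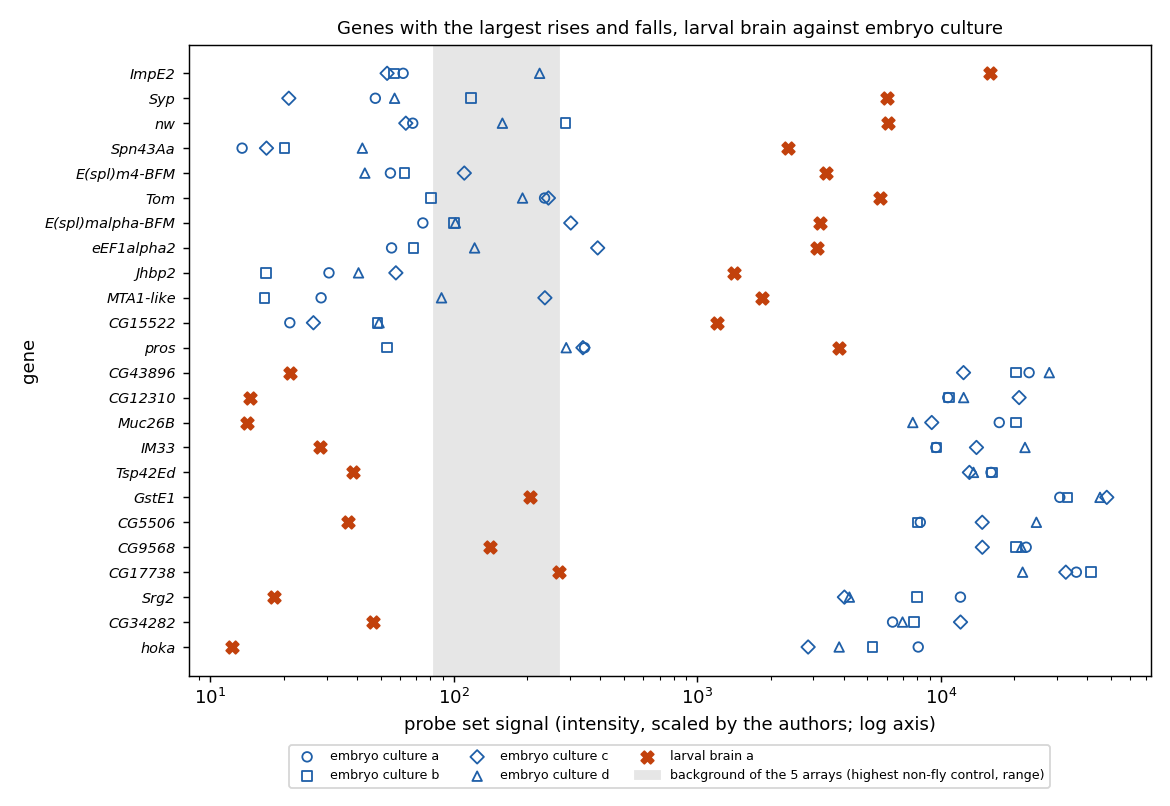
Probe set signal (intensity, log axis) of the 12 genes with the largest rises and the 12 with the largest falls that passed the test, with an open symbol for each of the 4 embryo culture arrays and a cross for the larval brain array. The grey band spans the background of the 5 arrays, from 82.6 to 271, and every larval brain value lies outside the embryo culture range of its gene.

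In all, 455 of 13966 probe sets passed the limma test, 121 higher and 334 lower in larval brain, and 2239 had an unadjusted p under 0.05. By gene, 88 rose and 302 fell, out of 10844. Larval brain was at or under background for 146 of the lower calls, and all embryo culture arrays were at or under background for 58 of the higher calls. The count depends on single arrays: without embryo culture array b it was 292, and the higher calls numbered 63, 59 and 70 without a, b and c. With a pseudocount at the 40th percentile, 39.0% of the calls were higher in larval brain, against 26.6% here, and limma without the variance trend called 303.

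RNA quality was seen only through 3′ to middle and 3′ to 5′ ratios of control transcripts, and what sets these ratios was not tested. The embryo culture arrays were not alike in them, and the larval brain array lay outside the embryo culture range for 3 control messenger RNAs. The signal of a control transcript at its 3′ end, over that at its middle or 5′ end, grows as the 5′ side is lost. All middle probe sets lay above background. For eIF-4a the 3′ to middle ratio was 8.39, 4.60, 2.59 and 3.55 on embryo culture arrays a, b, c and d and 2.03 on the larval brain array. For GAPDH it was 4.18, 5.14, 3.22, 3.25 and 2.53 in the same order, and for actin 4.65, 5.55, 2.68, 2.73 and 2.11. The 5′ probe sets lay at or under background for 8 of 12 values in embryo culture, all those of a and b among them, where the 3′ to 5′ ratio is only a lower bound. That ratio was at least 149, at least 125, 181, 74.3 and 27.1 for eIF-4a, at least 129, at least 87.5, 45.8, at least 83 and 7.89 for GAPDH, and at least 115, at least 91, 85.0, at least 42 and 31.3 for actin. The 18S ribosomal RNA, not a messenger RNA and left out of the indices below, differed in part: its 3′ to middle ratio was 4.592, 5.713, 2.410 and 2.167 on a to d and 3.133 on the larval brain array, inside the embryo culture range. Its 3′ to 5′ ratio was 59.3, 85.8, 25.4, 15.7 and 5.33, with each 5′ signal above background. Group and 3′ bias therefore differ together by most of these ratios, and medians against arrays a and b and against c and d are given beside the gene lists.

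A mean log2 ratio of the 3 transcripts was used as a covariate in 3 forms. The 3′ to middle index was 2.450, 2.345, 1.495 and 1.660 on embryo culture arrays a to d and 1.146 on the larval brain array. The 3′ to 5′ index was 8.69, 8.02, 6.48, 6.16 and 4.24 from the signals as they are, which lie at or under background for each 5′ end on a and b. With 5′ signals under background set to background (the floored index) it was 7.025, 6.641, 6.475, 5.993 and 4.237. Each fit extrapolates beyond the embryo culture range and is less precise: the median SE went from 0.581 to 0.708 with the 3′ to middle index, 0.861 with the 3′ to 5′ index and 1.54 with the floored index. Among the 20 list members named further on as past the threshold, and not among the 12 largest changes either way, 9 stayed so with the 3′ to middle index: nerfin-1, Nplp2, Tig, Idgf2, Idgf3, Idgf4, Jon65Aiv, PGRP-LB and AttD. The 3′ to 5′ index also ended the calls of Nplp2 and Jon65Aiv, which left 7, and the floored index left 0. The median absolute log2 difference of the 20 went from 3.04 to 3.15, 3.14 and 2.74 in these fits and their median SE from 0.52 to 0.59, 0.71 and 1.28, so that most calls ended with lower precision. Nplp2 also shrank, from -5.57 ± 0.95 to -3.39 ± 0.60 with the 3′ to middle index and -2.15 ± 0.55 with the 3′ to 5′ index.

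Quantile normalization and median centring each ended the calls of NPF, Burs, Mdr65, Mtk, AttD and MTA1-like, and the former also that of pros. Another pseudocount ended those of eya, tll and MTA1-like (5th percentile) and of NPF, Burs, Mdr65 and Mtk (40th percentile). Leaving out the variance trend ended those of Nplp2, Burs, tll, Mtk, AttD, eEF1alpha2, MTA1-like and pros. With embryo culture arrays c and d alone, those of NPF, Burs, tll, Fmr1, Mdr65 and ImpE3 were lost.

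**Figure D2:**
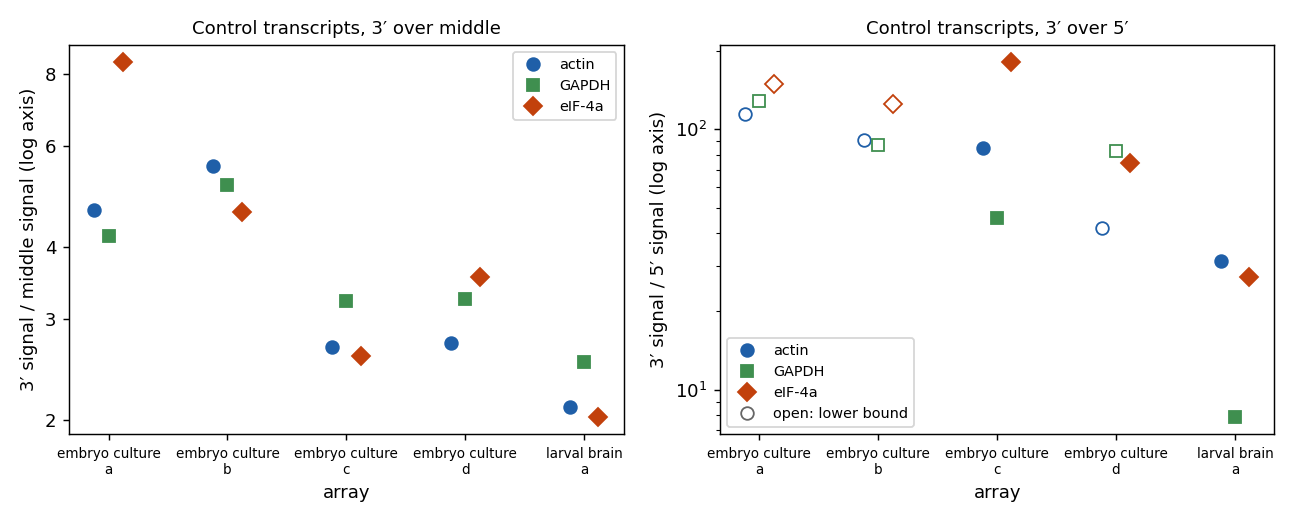
Ratio of 3′ to middle (left) and 3′ to 5′ (right) probe set signal (log axes) of the control transcripts actin, GAPDH and eIF-4a on each of the 5 arrays, 1 point per transcript and array. Open symbols are lower bounds, where the 5′ signal was at or under background. The larval brain array has the lowest ratios for each transcript, on the left 2.11, 2.53 and 2.03.

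Correlations of log2 signal across probe sets, which are not independent replicates, ranged from 0.837 to 0.933 between embryo culture arrays and from 0.738 to 0.802 between these and larval brain. The highest, 0.933, was between a and b. When each embryo culture array was set against the other 3 with the same limma fit, 0 probe sets passed for a, b, c or d, with 346, 386, 652 and 1537 at an unadjusted p under 0.05. Larval brain against the same sets of 3 gave between 292 and 403 calls.

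Progenitor and cell division genes were higher in larval brain. Of 18 measured neuroblast and progenitor genes, 15 had positive differences (median log2 1.52), 3 rose past the threshold over all probe sets and 8 rose when adjusted over the list alone. The 3 were pros, the Notch target E(spl)mdelta-HLH, at least 9.17-fold, from 87.6 ± 26.4, at or under background on all embryo culture arrays, to 1613 (adjusted p = 0.0182), and nerfin-1, a zinc finger gene of early neurons, from 374 ± 66.1 to 3658 (3.15 ± 0.44, adjusted p = 0.00569). The list stood apart by camera (adjusted p = 2.46e-05; adjusted p = 0.247 with an estimated correlation). All 20 measured cell cycle genes had positive differences (median log2 1.45), with 0 past the threshold over all probe sets and 6 adjusted over the list alone. The cell cycle list had an adjusted p of 1.35e-06 by camera, and adjusted p = 0.247 with an estimated correlation. Its brightest members were PCNA, a DNA replication factor, with 1295 ± 473 in embryo culture and 2235 in larval brain, and the mitotic cyclin gene CycB with 891 ± 255 and 2100. The progenitor medians were 1.43 against embryo culture arrays a and b and 1.20 against c and d, and the cell cycle medians were 1.56 and 1.19. With the 3′ to middle, 3′ to 5′ and floored indices as a covariate the progenitor median was 0.99, 1.05 and 0.69 and the cell cycle median 1.15, 0.81 and 0.50. Both calls were lost with the floored index alone of these (adjusted p from 1.18e-05 to 0.486 and from 3.06e-07 to 0.486 over 19 alternatives).

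Pan-neuronal genes and brain transcription factors were higher in larval brain. The pan-neuronal list was higher in larval brain by camera (12 genes, 9 positive, median log2 0.69, adjusted p = 0.0154; adjusted p = 0.25 with an estimated correlation). It had 1 member past the threshold, nerfin-1, which is also on the progenitor list, and 1 adjusted over the list alone. Its median was 0.86 against arrays a and b and 0.59 against c and d, and with the 3′ to middle, 3′ to 5′ and floored indices it was 0.57, 0.01 and -1.35, fits in which the call was lost. Over 19 alternatives its adjusted p ran from 0.0111 to 0.984. Brain and optic lobe transcription factors followed (17 genes, 11 positive, median 0.80, camera adjusted p = 0.0228; adjusted p = 0.391 with an estimated correlation). Of these, 2 rose over all probe sets and 4 adjusted over the list alone. They were eya, an eye and brain patterning gene, at least 6.68-fold higher (adjusted p = 0.0443), and tll, a nuclear receptor gene of the embryonic brain, at least 1.10-fold higher (adjusted p = 0.0428), both at or under background on all embryo culture arrays. The median of this list was 0.95 against a and b and 0.55 against c and d, where the call was lost, as it was with dim probe sets left out and with each of the 3 indices as a covariate (adjusted p from 0.0109 to 0.984 over 19 alternatives). The call of eya was lost without any 1 of the 4 embryo culture arrays (adjusted p up to 0.0861), and that of tll without a, b or c (up to 0.119).

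Hormone response and heat shock genes were higher in larval brain. In the ecdysone and hormone response list, 13 of 18 genes had positive differences, 3 rose over all probe sets and 5 adjusted over the list alone. Besides ImpE2 these were ImpL1 (at least 7.05-fold, adjusted p = 0.0299) and ImpE3 (at least 2.09-fold, adjusted p = 0.021). The list's camera adjusted p was 0.0107, and adjusted p = 0.367 with an estimated correlation. The list's call was lost without embryo culture array a or c, with adjusted p-values from 0.00724 to 0.0627 when an array was left out. Those of ImpL1 and ImpE3 were lost without a or c as well, of ImpL1 also without d and of ImpE3 also without b, with adjusted p-values up to 0.0653 and 0.0721. The list call was also lost with arrays a and b alone, with dim probe sets left out, with each of the 3 indices as a covariate and by fry, so that 9 of 19 alternatives ended it (adjusted p from 0.00724 to 0.984). The median was 1.15 against arrays a and b and 0.36 against c and d. All 7 measured heat shock genes had positive differences (median 2.02), with 0 past the threshold over all probe sets and 4 adjusted over the list alone. The heat shock list had a camera adjusted p of 0.00139 (adjusted p = 0.247 with an estimated correlation). Hsp27, a small heat shock protein gene, stood at 2846 ± 2134 in embryo culture and 28113 in larval brain (adjusted p = 0.0541, and 0.0307 to 0.102 when an array was left out), and Hsp26 at 4974 ± 4128 and 24627. The median was 1.62 against a and b, 1.56 against c and d, and 0.91 with the 3′ to middle index. It was 0.46 with the 3′ to 5′ index and -0.75 with the floored index, where the call was lost (adjusted p from 0.000114 to 0.987 over 19 alternatives).

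Markers of fat body, gut, blood cells and immunity were lower in larval brain by camera, those of blood cells mainly against embryo culture arrays a and b. All 11 measured fat body and larval serum genes had negative differences (median log2 -1.74), 3 fell over all probe sets and 5 adjusted over the list alone (camera adjusted p = 5.38e-05; adjusted p = 0.247 with an estimated correlation). The 3 were Idgf2, Idgf3 and Idgf4, secreted chitinase-like growth factors. Idgf4 fell from 6119 ± 2617 to 466 (log2 difference -3.48 ± 0.55, adjusted p = 0.00991), Idgf3 from 3931 ± 812 to 399, and Idgf2 at least 15.7-fold. The fat body medians were -2.00 against arrays a and b, -1.48 against c and d, -1.39 with the 3′ to middle index and -1.16 with the 3′ to 5′ index. With the floored index the median was 0.08 and the call was lost (adjusted p from 1.94e-05 to 0.584 over 19 alternatives). In the antimicrobial and immune list, 10 of 11 genes had negative differences (median -1.82), 3 fell over all probe sets and 4 adjusted over the list alone (camera adjusted p = 0.000406; adjusted p = 0.25 with an estimated correlation). They were the antimicrobial peptide genes Mtk, at least 11.9-fold lower (adjusted p = 0.0408), and AttD, from 2777 ± 1233 to 393 (adjusted p = 0.0286), and PGRP-LB, a peptidoglycan recognition protein gene, from 1260 ± 319 to 119 (adjusted p = 0.00819). The immune medians were -1.51 against a and b, -1.60 against c and d, and -1.30 with the 3′ to middle index. They were -0.33 with the 3′ to 5′ index and 0.765 with the floored index, where the call was lost (adjusted p from 1.94e-05 to 0.987 over 19 alternatives). The call of Mtk was lost without array a, b or c and that of AttD without c, with adjusted p-values up to 0.0734 and 0.0661.

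Of 23 midgut genes, which encode digestive enzymes, 19 had negative differences (median -0.79), 1 fell over all probe sets and 2 adjusted over the list alone (camera adjusted p = 0.00139; adjusted p = 0.25 with an estimated correlation). The 1 was the serine protease gene Jon65Aiv, from 1362 ± 261 to 144 (log2 difference -2.86 ± 0.42, adjusted p = 0.00673). The midgut median was -0.90 against a and b and -0.70 against c and d, where the call was lost, as it was with the 3′ to 5′ index and the floored index but not with the 3′ to middle index (adjusted p from 0.00106 to 0.836 over 19 alternatives). Of 19 hemocyte (blood cell) genes, 16 had negative differences (median -1.06), 1 fell over all probe sets and 3 adjusted over the list alone (camera adjusted p = 0.0107; adjusted p = 0.693 with an estimated correlation). Tig, which encodes the matrix protein Tiggrin, fell from 1184 ± 298 to 24.6, which is background, at least 14-fold (adjusted p = 0.00189). The hemocyte median was -1.81 against arrays a and b but -0.27 against c and d, where the call was lost, as it was with dim probe sets left out, and it turned to 0.32, 0.94 and 2.05 with the 3′ to middle, 3′ to 5′ and floored indices, in the last past the threshold (adjusted p from 7.86e-06 to 0.693 over 19 alternatives). This list also differed among the embryo culture arrays themselves, with a median of -1.32 for c and d minus a and b. These pairs differ in the 3′ ratios of the control transcripts, but the labels do not say what else differs between them. The cause was not tested. Of the 10 lists called by camera, fry's directional test passed 4: the progenitor, cell cycle, fat body and midgut lists.

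**Figure D3:**
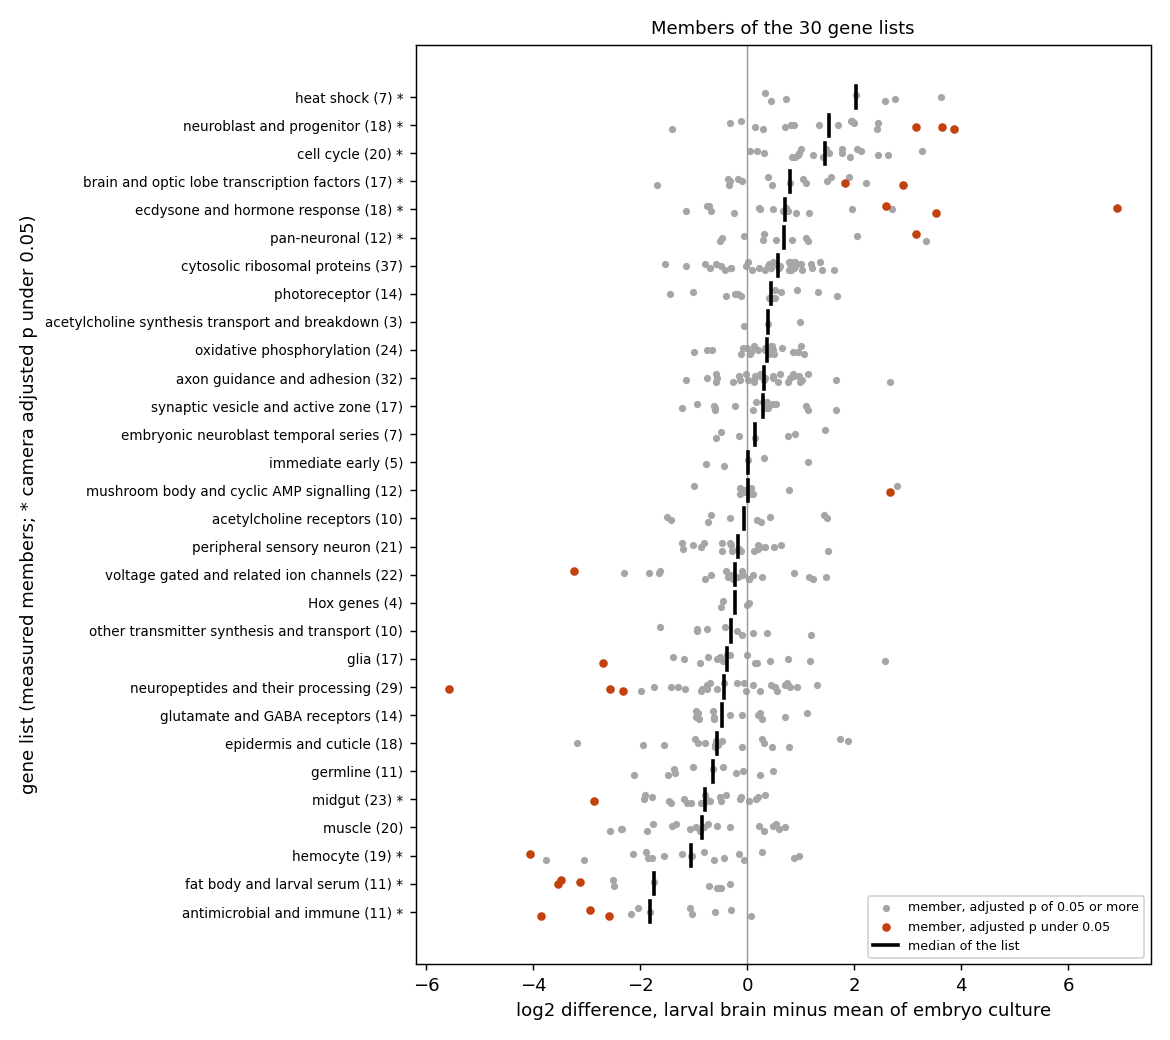
Log2 difference, larval brain minus the mean of embryo culture, for the measured members of the 30 gene lists, 1 point per gene, with the list median as a black bar and members past the limma threshold in orange. Lists with an asterisk passed camera with the preset correlation, and their medians run from -1.82 for the antimicrobial and immune list to 2.02 for the heat shock list.

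The other 20 lists did not pass camera, and their members past the limma threshold over all probe sets were few. Among 29 neuropeptide and processing genes, 3 fell in larval brain and 6 adjusted over the list alone. Nplp2 fell from 10420 ± 8090 to 116 (log2 difference -5.57 ± 0.95, adjusted p = 0.0146), the neuropeptide F gene NPF at least 5.20-fold (adjusted p = 0.0422), and Burs, which encodes a bursicon subunit, from 653 ± 185 to 89.7 (adjusted p = 0.0466). The calcium-activated potassium channel gene slo fell at least 5.67-fold (adjusted p = 0.0157), 1 of 22 ion channel genes, and 1 passed adjusted over the list alone. Mdr65, a blood-brain barrier transporter gene of glia, fell at least 4.45-fold (adjusted p = 0.0414), 1 of 17 glial genes, and 1 passed adjusted over the list alone. Fmr1, which encodes an RNA-binding protein, rose at least 2.02-fold (adjusted p = 0.00721), 1 of 12 mushroom body and cyclic AMP genes, with 2 adjusted over the list alone. The axon guidance (32 genes), synaptic vesicle (17), muscle (20), ribosomal protein (37), oxidative phosphorylation (24), glutamate and GABA receptor (14), photoreceptor (14), peripheral sensory neuron (21), epidermis (18), germline (11), Hox (4), temporal series (7) and immediate early (5) lists had 0 members past the threshold, over all probe sets or adjusted over the list alone. The list of other transmitters (10 genes) had 0 over all probe sets and 1 adjusted over the list alone, Ddc, a dopamine and serotonin synthesis gene, with 6598 ± 1626 in embryo culture and 2053 in larval brain (adjusted p = 0.0908 over all probe sets). Camera adjusted p-values of these 20 lists ran from 0.0906 to 0.958. Without array c the ribosomal protein and oxidative phosphorylation lists passed, at 0.0116 and 0.0176 and higher in larval brain, as they did with a and b alone (from 0.00012 to 0.709 and from 0.00702 to 0.984 over 19 alternatives), and without d the muscle list passed at 0.0203 and was lower. With the 3′ to middle index the neuropeptide list passed and was lower, with adjusted p-values from 0.0444 to 0.584 over 19 alternatives. The ribosomal protein median was 0.80 against arrays a and b and 0.09 against c and d. The calls of NPF, Burs and Mdr65 were lost without any 1 of the 4 embryo culture arrays, with adjusted p-values up to 0.114, 0.132 and 0.109, and that of slo without b, at 0.0531.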

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

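The tests of dividing progenitors and of single arrays as the lone sample were chosen after their results had been seen, and so were the fits with an index of 3′ bias as a covariate, and the 3′ to middle and floored indices. The other tests of explanations here were written before their results were seen.

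Some named values lay far from the other embryo culture arrays. ImpE2 read 225 on array d against 53.2 to 61.9 on the others, tll 41.4 on d against 13.1 to 16.4, ImpE3 52.7 on d against 11.9 to 16.3, and cas, a neuroblast temporal gene, 37.1 on d against 172 to 209. The gene pros read 53.1 on array b against 290 to 344, nAChRbeta2 982 on c against 1362 to 1411, and rdgA, a photoreceptor gene, 127 on a against 615 to 677. Chance alone flags about 1 in 20 sets, and 7 flagged among 119 tested is near that rate. Array d accounted for 4 of the 7. Background was also highest on d, at 271, and the d values of ImpE2, tll, ImpE3 and cas lie under it. For ImpE2, tll and ImpE3 the values on the other embryo culture arrays lie at or under background as well.

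Midgut, fat body and immune genes were higher in embryo culture. If 3′ bias alone caused this, the difference against arrays c and d would be a share of that against a and b, in proportion to the control index. The bound written beforehand, 0.506, came from the 3′ to 5′ index, but its 5′ signals on a and b lie at or under background, so that share is not measured. With every 5′ signal under background set to background, those of actin and GAPDH on d included, the share is 0.769. It rests on lower bounds, so it is not measured either. By the 3′ to middle index the share is 0.345. The observed ratio was 0.681 (95% bootstrap interval 0.519 to 1.14, 45 genes). The interval lies above 0.506, which would have counted against 3′ bias, but that bound was set aside. It spans 0.769 but not 0.345, so it does not decide. Only genes were resampled, so the interval leaves out the spread between arrays and takes the genes as independent. With the 3′ to middle index as a covariate, 3 of the 3 lists stayed past the threshold, with the 3′ to 5′ index 1 and with the floored index 0, where the immune median went from -1.82 to 0.765 with a median SE of 1.344 for its members against 0.528. The larval brain index lies outside the embryo culture range in each form, so bias and source cannot be told apart for these genes. Gut cells that passed the sort for GFP, which should remove them, may be a source: of 21 further intestine genes 15 had negative differences, but their median of -0.593 did not stand apart by camera (p = 0.209, and p = 0.512 with an estimated correlation), and the brightest, Bace, stood at 6883 ± 5428 in embryo culture and 322 in larval brain (limma adjusted p = 0.0729).

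Progenitor and cell cycle genes were higher in larval brain. The ratio for these 38 genes was 0.825 (0.625 to 1.08). It lies above the 0.506 written beforehand, which would have counted against 3′ bias, but that bound was set aside as for the gut genes, because its 5′ signals on a and b lie at or under background. The interval spans the 0.769 of the floored index but not the 0.345 of the 3′ to middle index, and it too leaves out the spread between arrays. Both lists stayed past the threshold with the 3′ to middle index as a covariate, but the larval brain index lies outside the embryo culture range. That fit extrapolates, so it does not decide on 3′ bias. With the floored index both calls were lost, and the cell cycle median went from 1.446 to 0.498 while the median SE of its members went from 0.61 to 1.589. A loss further toward the 5′ end is measured only in part, with 8 of 12 control 5′ values in embryo culture at or under background, so 3′ bias stays open. Dividing progenitors among the sorted larval brain cells, which sorting for the driver should remove, stay open: the cell cycle median of 1.446 is part of the pattern itself and cannot decide for them. The age of the cells and culture itself also differ between the sources and were not tested.

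With 5 arrays there are 5 choices of a lone array, too few for a share under 0.05. The larval brain array gave 455 limma calls, and the highest of the other choices gave 0, with 220 to 1039 probe sets at an unadjusted p under 0.05 in those 4 fits, so 1 of the 5 choices gave as many.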

How the results depend on the processing

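Fits with embryo culture arrays c and d alone, with a and b alone, and with an index of 3′ bias as a covariate (3′ to 5′, floored or 3′ to middle) were chosen after the data were seen. The 455 calls (121 higher, 334 lower in larval brain) became 303 (77 higher) without the variance trend, and 292 to 403 (59 to 91 higher) when an embryo culture array was left out, the lowest without b. They became 796 (305 higher) with c and d alone, 1732 (779 higher, 953 lower) with a and b alone, 264 (65 higher, 199 lower) with the 3′ to 5′ index, 408 (96 higher, 312 lower) with the 3′ to middle index and 2 (0 higher, 2 lower) with the floored index, where the median SE was 1.54 against 0.581. The count with no test, of probe sets 2-fold different and outside the embryo culture range, was 3556 (1762 higher, 1794 lower), and a single embryo culture array against the other 3 gave 1503 to 2651 by that rule, where larval brain against the same sets of 3 gave 3579 to 4023. With a and b alone, or c and d alone, the spread comes from a single pair of arrays, so the higher counts there are not stronger evidence. The median SE was 0.415 with a and b, the most alike pair (correlation 0.933), and 0.703 with c and d. The cause of these shifts was not tested. Median centring moved the median difference of all probe sets from -0.0746 to 0.0472. Of the 10 lists called by camera, 3 were called with the 3′ to 5′ index, 6 with the 3′ to middle index (7 lists in all), 1 with the floored index (hemocyte, reversed), 0 with an estimated correlation and 4 with fry's directional test. The hemocyte list reversed with the 3′ to 5′, floored and 3′ to middle indices, to medians of 0.938, 2.054 and 0.317. With the floored index the pan-neuronal and immune lists and Nplp2 also reversed, to -1.349, 0.765 and 1.373, and the fat body, heat shock and brain transcription factor medians changed sign, to 0.084, -0.745 and -0.223, while camera kept their direction. The immediate early gene sr, with no difference to reverse in the main fit (0.021 ± 0.753), went to -1.807 ± 0.373 with the 3′ to middle index. With that index the ecdysone median became -0.004. The cause of these was not tested. The median correlation between embryo culture arrays fell to 0.819 when dim probe sets were left out, a narrower range of levels. Over all alternatives, the 10 called lists kept their call and direction in 144 of 190 results and the 44 called genes in 547 of 698. Lists and genes not called stayed so in 373 of 379 and 1101 of 1132. Of the 24 genes with the largest changes, 14 kept their call with the 3′ to 5′ index, 19 with the 3′ to middle index and 2 with the floored index. No paired analysis was possible because the groups share only the letter a. Signal over background limits what can be seen: 48.6% of probe sets on array d and 68.0% on the larval brain array lay above it.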

Other observations

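The families, the smooth septate junction list and every gene named in this part were chosen after the results had been seen, and the tests on them are of that kind. The medians of larval brain minus all embryo culture arrays kept their sign, for each family and list named, with each pseudocount, with quantile normalization and with median centring.

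The Cyp, GstE, GstD and Tsp gene families were lower in larval brain. In a scan of 146 families of at least 5 genes, formed from the letters their symbols start with, 21 passed camera over all families and 0 with an estimated correlation. Among 83 genes with symbols that start with Cyp, which are cytochrome P450 genes apart from the cyclophilin genes Cyp1 and Cyp40, 72 had negative differences and 14 fell by limma (camera adjusted p = 2.13e-09; adjusted p = 0.548 with an estimated correlation). Cyp6a20 fell from 3360 ± 1101 to 6.1, at least 39.0-fold, and Cyp9b2 at least 45.5-fold. Of 14 GstE and 11 GstD glutathione S-transferase genes, 6 and 4 fell, with camera adjusted p-values of 8.64e-07 and 1.42e-05 (adjusted p = 0.548 and adjusted p = 0.6 with an estimated correlation). GstD2 fell from 22180 ± 11280 to 435. Of 31 tetraspanin genes (Tsp), 29 had negative differences and 8 fell (camera adjusted p = 4.77e-06; adjusted p = 0.548 with an estimated correlation). By fry's directional test the adjusted p was 0.0401 for Cyp, 0.0322 for GstE, 0.0322 for Tsp and 0.0515 for GstD. The Cyp, GstE and Tsp medians for embryo culture arrays c and d minus a and b were 0.00, 0.17 and 0.01, and that of GstD was 0.50. Counts of signs are weak evidence for dim genes, since background was lowest on the larval brain array, at 82.6. The Gr, Ir and Or families, with 0 calls and not past camera, had 25 of 28, 34 of 43 and 38 of 52 genes lower. The median difference of all probe sets was -0.0746, and 0.1555 with dim ones left out. The same limit applies to the midgut and further intestine genes.

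Notch target, mitochondrial ribosome and nuclear pore genes were higher. All 9 measured E(spl) genes had positive differences (median log2 2.87) and 4 rose, among them E(spl)m7-HLH from 536 ± 97.3 to 4801 (limma adjusted p = 0.005; for the family, camera adjusted p = 1.56e-06, and adjusted p = 0.6 with an estimated correlation). Their medians were 3.24 against arrays a and b and 1.98 against c and d. Of 43 mRpL genes, 42 had positive differences (median 0.75), as did 19 of 20 nucleoporin (Nup) and 18 of 20 Mediator (MED) genes (medians 0.98 and 1.13), with 0 past the limma threshold in each family. Their camera adjusted p-values were 2.57e-05, 6.19e-05 and 2.97e-05, and adjusted p = 0.548 with an estimated correlation in each. The mRpS genes, also of the mitochondrial ribosome, were positive in 21 of 21 (median 0.83, camera adjusted p = 0.000712, and 0.6 with an estimated correlation). By fry's directional test the adjusted p was 0.0401 for Nup, 0.05 for mRpL, 0.0515 for E(spl), 0.0549 for MED and 0.167 for mRpS.

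Genes of the smooth septate junction, the cell junction of the fly gut, were lower in larval brain by a wide margin. All 4 fell by limma: mesh from 8678 ± 3169 to 438, Ssk from 11640 ± 4077 to 566, Tsp2A from 3549 ± 1485 to 473, and hoka as described. The median log2 difference was -4.12 against arrays a and b and -4.17 against c and d. Other gut-associated genes that fell were mex1, at least 34.6-fold, from 2901 ± 569 to 30.1 (adjusted p = 0.000333), Peritrophin-15b, at least 30.2-fold, from 2574 ± 799 to 51.8, and Hnf4, from 1448 ± 326 to 324 (adjusted p = 0.0386). These genes were picked because they fell, so they do not test the gut cell explanation, for which the further intestine genes gave a median of -0.593.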
